A study of Homo sapiens with 18 samples.

How the data were processed

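Per the labels, OVCA433 ovarian cancer cells were transduced by lentivirus and sorted by fluorescence for RFP, GFP or both, and 18 libraries of polyadenylated RNA were made, 3 in each of 6 groups. Per the labels' protocols, RNA was accepted at an RNA integrity number of 7 or more, and 2 libraries with 6.9 were included. Per the submitters' processing notes, Cufflinks and DESeq were used with the human genome build hg19. Versions of these tools, the aligner, the read counting tool and the gene models are not given in the sources used here. The ARID3A construct is a fusion with GFP and the ARID3B construct came with RFP, per the labels.

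The authors deposited a table of average FPKM (fragments per kilobase of transcript, scaled to library size) with a column for each of the 5 transduced groups, each the mean of a group's libraries per the file headers. All 5 columns were matched to series groups by their headers, and 0 columns belonged to no sample of the series. The authors also deposited 5 comparisons of a group with the RFP+GFP control, each with a log2 fold, a p-value and a corrected p-value per RefSeq transcript. Per the file headers these list features with an average read count above 10 and a p-value under 0.05 only. The corrected p-value is not explained in the sources used here. It was checked to follow Benjamini-Hochberg over 38017, 37349, 37315, 37043 and 38994 features, for ARID3A-GFP, ARID3B+RFP and the populations labelled high/high, high/low and low/high, by whole ranks within 0.002 over the first 400 features. The highest corrected p-value listed was 0.0957, 0.103, 0.137, 0.232 and 0.0849, so the lists reach past the threshold of 0.05 used here. Values per library, raw counts and FPKM of the control were not used here. The depth per library is therefore unknown, and no interval, SD or test over libraries was computed between transduced groups.

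The FPKM table held 26914 entries for 25387 RefSeq accessions, and the 1527 repeated entries, which place a transcript at several loci, were averaged per accession. The comparisons held 8509, 7766, 5699, 3210 and 9732 entries and, reduced to genes, 8482, 7749, 5683, 3202 and 9701. Symbols turned into dates (15, 13, 10, 6 and 13 entries) were left out. Genes listed in both directions within a comparison (6, 2, 4, 1 and 9, which are 14 genes in any comparison) were left out as well. A gene was called at the authors' corrected p-value under 0.05. The control FPKM was implied as group FPKM divided by the deposited fold. Comparisons and FPKM were joined by gene symbol. Of the listed transcript accessions 76.4, 86.5, 78.0, 78.4 and 77.5% were in the FPKM table. A fold and an FPKM, or the folds of 2 comparisons, may therefore be of different transcripts of a gene, which also limits the implied control levels. Genes with an FPKM of 0 got no fold from FPKM. Group FPKM were compared as log2 ratios with a pseudocount of 1 FPKM among genes of at least 1 FPKM.

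The design, the comparisons, the gene lists, the rule for named genes and most alternative settings were chosen before the data were examined. For each comparison the rule named the 10 raised and the 10 lowered genes with the largest folds among called genes with a plain gene symbol, at least 1 FPKM in the higher group (in place of 50 counts, since counts were not used) and a level above 0 in both. For each list it named up to 4 called members with the smallest adjusted p-value, for overlaps the 6 genes per direction with the largest smaller fold, and for the populations carrying both proteins the 6 per direction with the largest range. ARID3A, ARID3B, TNF, PROM1, CD44 and ALDH1A1 were always named. Some genes that the rule names are not reported here.

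The 28 lists, of 875 entries, were stem cell and cancer stem cell markers, epithelial genes, mesenchymal transition genes, G1/S genes, G2/M genes, p53 target genes, apoptosis and death receptor genes, NF-kB target genes, interferon response genes, MHC class I and II genes, Wnt pathway genes, Notch pathway genes, TGF-beta and BMP pathway genes, Hedgehog pathway genes, growth factor receptors and MAPK response genes, integrins, collagen and basement membrane genes, hypoxia and glycolysis genes, sterol synthesis genes, unfolded protein and integrated stress response genes, HOX genes, ARID family genes, ovarian carcinoma markers, replication-dependent histone genes, cytosolic ribosomal protein genes, nuclear respiratory chain genes, fibroblast and mesothelial markers, and leukocyte and endothelial markers. A member was measured if it belonged to the background of 14195 genes, which have at least 1 FPKM in a group or are listed in a comparison. Members raised or lowered were tested against the other genes of the same comparison by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over 280 tests. Counts adjusted over the list alone used Benjamini-Hochberg on the deposited p-values of the list's members. The planned percentile of a list's median fold was not run, since the comparisons list selected genes only. List ratios of FPKM were ranked among 10000 random lists matched on level. Genes are not independent replicates, so list tests describe the lists and do not test the groups.

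Overlaps were set against the product of the margins over genes listed in both comparisons, and against 100 simulations of unchanged groups that share a control. The populations carrying both proteins were regressed across genes on the sum of the single folds, and the same regression was run on 100 simulations of unchanged groups that share a control, a step added after the data were seen. Gene order came from RefSeq positions (GRCh38.p14) and GC content and length from the longest GENCODE v29 transcript, since gene models of hg19 were not used, and no coordinate was taken from these. At least 91.5% of the listed genes of each comparison were placed and 94.0% of the genes had a GC value. Chromosome shares were set against 1000 shuffles of direction within bins of GC content. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

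The settings chosen in advance were adjusted p thresholds of 0.01 and 0.1, a minimum log2 fold of 1, a minimum of 10 FPKM and another pseudocount. Alternatives added after the data were seen were at least 1 FPKM in the higher group, recentred folds, counting each listed transcript, all expressed genes as the background of list tests, leaving out the population labelled high/low from the genes called in all 5, and leaving out chromosomes 4, 6 and X. Lists were also set against random lists matched on chromosome, or on GC content and length, after the data were seen. The list test was tested on simulated data: without an effect it called 4, 3.5, 4.5, 2.5 and 4.5% of 200 simulations over 8482, 7749, 5683, 3202 and 9701 genes, and with an effect 100%. Calls were shuffled over genes there, so these rates leave out the correlation of real calls with GC content and along chromosomes. The simulated effect raised most members of a list, so the 100% does not speak to weaker effects. The test of chromosome shares called 1.74% without an effect and 100% with one on 7781 genes in 10 simulations. The neighbour correlation called 0% and 100% on the same genes, and lists matched on GC content called 2% and 100% of 50 simulations on 11347 genes.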

Results

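OVCA433, an established human ovarian cancer cell line, was transduced by lentivirus with ARID3A, ARID3B or both, and polyadenylated RNA was sequenced after cell sorting. ARID3A and ARID3B are paralogous DNA-binding proteins of the AT-rich interaction domain family. The 18 libraries fell into 6 groups of 3. The control group carried RFP and GFP, a group carried ARID3A-GFP, a group carried ARID3B with RFP, and the other 3 carried both proteins and were sorted into populations labelled by the level of each. These populations are written here as labelled high/high, high/low and low/high, with ARID3A first. The values used were the authors' mean FPKM for the 5 transduced groups and the authors' DESeq comparison of each group with the control. Values per library and FPKM of the control were not used here, so the depth of each library is unknown, no SD is given, and differences between transduced groups were not tested. The p-values of the comparisons with the control measure only the spread between these samples, which may be technical. Those of the list tests set genes against other genes and measure no spread between samples.

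ARID3A and ARID3B, the genes delivered by the virus, were measured in every group to relate each population to its label. ARID3A was raised in all 5 groups, the one labelled ARID3B+RFP included, and ARID3B was raised most in the population labelled high/low. The levels therefore went against the labels, and reads of the transgene and of the cell's own gene were not separated. Mean ARID3A was 435 FPKM in the libraries labelled ARID3A-GFP, 236 FPKM in those labelled ARID3B+RFP, and 425, 345 and 488 FPKM in those labelled high/high, high/low and low/high. Its log2 folds over the control in the authors' deposited table were 6.66, 5.94, 6.71, 6.38 and 6.94. In the same order, mean ARID3B was 7.76, 30.2, 14.5, 68.9 and 13.5 FPKM, and its log2 folds in the authors' deposited table were 1.11, 3.13, 2.16, 4.27 and 1.86. The adjusted p from the authors' DESeq with Benjamini-Hochberg was highest at 1.94e-53 for ARID3A, in the population labelled high/low, and at 8.10e-09 for ARID3B, in the population labelled high/high. The control levels implied by group FPKM and fold were 3.85 to 4.31 FPKM for ARID3A and 3.25 to 3.73 FPKM for ARID3B. The population labelled high/low held 0.707 times the ARID3A and 5.10 times the ARID3B of the population labelled low/high, and the libraries labelled ARID3B+RFP held 0.543 times the ARID3A of those labelled ARID3A-GFP. The third paralog, ARID3C, lay between 0.0844 and 0.190 FPKM and was listed in no comparison. Every direction given below for a group rests on these labels.

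**Figure D1:**
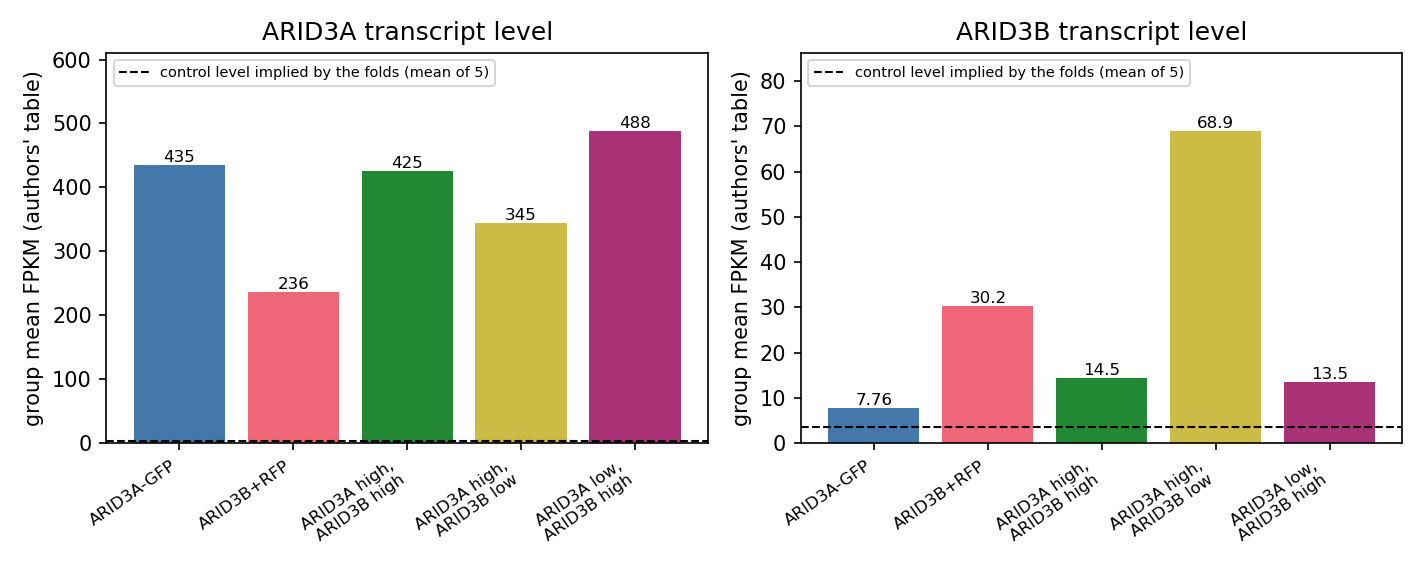
Mean FPKM of ARID3A and of ARID3B in the 5 transduced groups, as bars of the authors' group means with no error available. The dashed line is the control level implied by the folds, ARID3A lies between 236 and 488 FPKM in all 5 groups, and ARID3B is highest, at 68.9 FPKM, in the population labelled high/low.

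The libraries labelled ARID3A-GFP were compared with the control to find genes that follow ARID3A, with the limit that ARID3B was raised in them as well. CCND2, a cyclin of the G1 phase, rose, as did TIMP3, an inhibitor of matrix metalloproteinases, GLI2, a transcription factor of the Hedgehog pathway, and GRB10, an adaptor of insulin receptor signalling. The focal adhesion gene TNS1, FAM155B, the gelatinase MMP2, the matrix proteoglycan VCAN and the placental-type alkaline phosphatase ALPPL2, whose reads overlap those of its near copy ALPP, rose as well. HAPLN1, which links hyaluronan to proteoglycans, fell, together with the cytokine IL1A, the neutrophil chemokine CXCL1, the TNF-family ligand TNFSF12, the synaptic scaffold HOMER2 and the secretory kinase FAM20C. C1orf115, the nuclear factor TOX2, the regeneration-related NREP and MEIS3P1, a pseudogene whose reads overlap those of MEIS3, completed the strongest decreases. The log2 folds in the authors' deposited table were 8.32 for CCND2, 8.09 for TIMP3, 6.85 for GLI2, 6.85 for GRB10, 6.35 for TNS1, 6.35 for FAM155B, 6.13 for MMP2, 5.97 for VCAN and 5.54 for ALPPL2. On the lowered side the authors' deposited table gave -7.55 for HAPLN1, -6.63 for IL1A, -6.41 for CXCL1, -5.99 for TNFSF12, -5.83 for MEIS3P1, -5.78 for HOMER2, -5.60 for FAM20C, -5.51 for C1orf115, -5.47 for TOX2 and -5.43 for NREP. CXCL1 stood at 3.10 FPKM against an implied control of 264 FPKM. The authors' DESeq with Benjamini-Hochberg called 7781 genes at an adjusted p under 0.05, of which 3759 were raised and 4022 lowered, and 2093 of the 7781 changed at least 2-fold.

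NF-kB target genes, which encode cytokines, chemokines and feedback inhibitors of inflammation, were lowered as a group in the libraries labelled ARID3A-GFP, with CSF1, the chemokine CXCL8 and the acute-phase protein SAA1 among them. Genes of mitosis fell too, including the cyclin CCNA2, the spindle checkpoint gene MAD2L1, the cytokinesis gene ANLN and the centrosome kinase NEK2. Targets of p53 rose, among them the antiproliferative BTG2 and the death effectors PMAIP1 and BAX, while the kinase PLK2 fell. Wnt pathway genes rose, with the ligand WNT5B and the receptor FZD2, although PORCN, which acylates Wnt proteins, fell. Of 27 measured NF-kB targets 22 were lowered and 3 raised, the counts being 22 and 3 when adjusted over the list alone, and their decrease exceeded that of the other listed genes (adjusted p 0.000833, two-sided Fisher's exact test with Benjamini-Hochberg over 280 list tests, used for every list below). Of 34 G2/M genes 21 were lowered and 0 raised, or 22 and 0 adjusted over the list alone (adjusted p 0.000612). The p53 targets counted 17 raised and 3 lowered of 26, or 18 and 3 adjusted over the list alone (adjusted p 0.0103), and the Wnt genes 21 and 5 of 38, with the same counts adjusted over the list alone (adjusted p 0.00350). The authors' deposited table gave log2 folds of -4.96 for CSF1, -4.60 for CXCL8, -3.46 for SAA1, -0.97 for CCNA2, -0.75 for MAD2L1, -0.60 for ANLN and -0.61 for NEK2. The authors' deposited table also gave 1.77 for BTG2, 1.04 for PMAIP1, 0.69 for BAX, 4.41 for WNT5B and 1.21 for FZD2, against -0.71 for PLK2 and -2.27 for PORCN. Among called genes 91.5% of the 364 on chromosome 4 were lowered. CCNA2 and MAD2L1 lie there, and their folds of -0.97 and -0.75 compare with a median log2 fold of -0.66 over those genes. Their decreases are therefore not separated from that of the chromosome. Off chromosomes 4 and 21, 17 of 22 NF-kB targets and 19 of 31 G2/M genes were lowered.

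**Figure D2:**
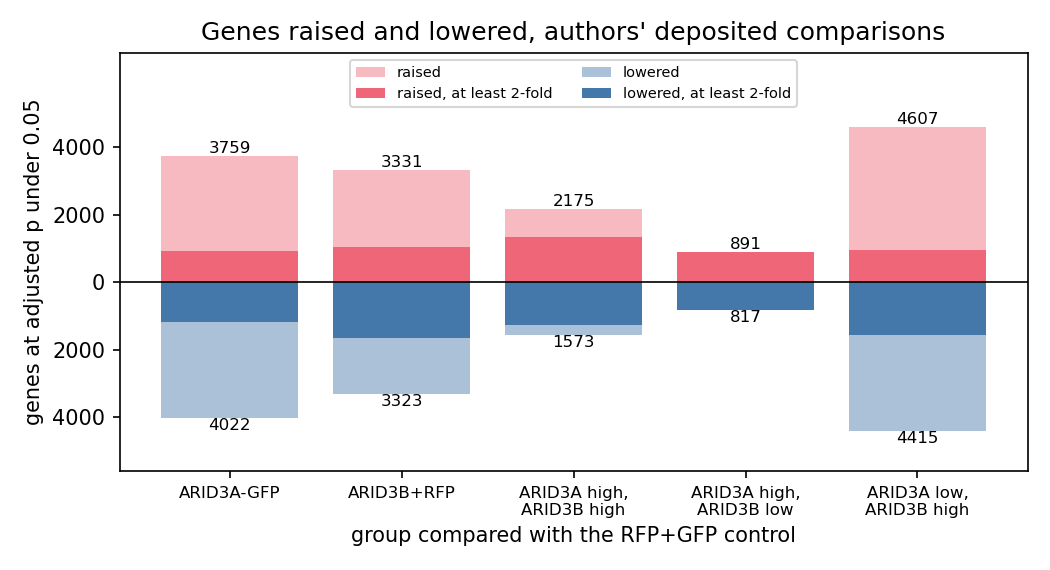
Genes raised (above 0) and lowered (below 0) at an adjusted p under 0.05 in each group against the RFP+GFP control, from the authors' comparisons, with the part changed at least 2-fold in darker shade. The counts run from 1708 genes in the population labelled high/low to 9022 in the population labelled low/high.

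The libraries labelled ARID3B+RFP were compared with the control to find genes that follow ARID3B, with the limit that ARID3A was raised in them as well. CCND2, TIMP3, GRB10, GLI2, FAM155B and TNS1 again led the raised genes, joined by XYLT1, which starts glycosaminoglycan chains, the small proteoglycan BGN, MMP2 and the metallothionein MT1E, a member of a family of near-identical genes. HAPLN1, CXCL1, IL1A and the inflammatory cytokine IL1B led the lowered genes. The prohormone convertase inhibitor PCSK1N, the Rac activator PREX1, the LIM protein FHL1, CYSTM1, NREP and MEIS3P1 followed. The authors' deposited table gave log2 folds of 8.96 for CCND2, 8.83 for TIMP3, 7.84 for GRB10, 7.54 for GLI2, 7.36 for FAM155B, 7.14 for TNS1, 7.07 for XYLT1, 6.24 for BGN, 6.21 for MMP2 and 6.12 for MT1E. It gave -8.19 for HAPLN1, -7.97 for CXCL1, -7.14 for IL1A, -6.99 for IL1B, -6.70 for MEIS3P1, -6.27 for NREP, -6.24 for PCSK1N, -6.12 for PREX1, -6.08 for FHL1 and -6.03 for CYSTM1 in the authors' deposited table. The authors' DESeq with Benjamini-Hochberg called 6654 genes, 3331 raised and 3323 lowered, of which 2722 changed at least 2-fold, 1061 raised and 1661 lowered.

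NF-kB targets were lowered as a group in the libraries labelled ARID3B+RFP, from CXCL8 to TNFAIP2, a gene induced by TNF. Genes of mitosis were lowered with the kinetochore genes CENPE and CENPF and the checkpoint kinase TTK. Epithelial genes rose, among them the keratin KRT8 and the junction gene LSR, and so did genes of the unfolded protein and amino acid stress responses such as DDIT4 and the transporter SLC7A5. NF-kB targets counted 3 raised and 19 lowered of 27, with the same counts adjusted over the list alone (adjusted p 0.000858). G2/M genes counted 0 raised and 16 lowered of 34, also adjusted over the list alone (adjusted p 0.000455). CENPE lies on chromosome 4 and TTK on chromosome 6, where 93.9 and 77.3% of called genes were lowered. Without chromosomes 4, 6 and X, 12 of the 13 G2/M members left in the comparison were lowered. Epithelial genes counted 13 raised and 2 lowered of 31 and stress response genes 13 and 4 of 30, with the same counts adjusted over the list alone (adjusted p 0.0287 and 0.0393). Against all expressed genes rather than the listed ones the rises of epithelial and stress genes no longer passed (adjusted p 0.0809 and 0.0680). G1/S genes, with 12 raised and 1 lowered of 34 in both counts adjusted over the list alone and over all genes, were lowered less often than other listed genes (adjusted p 0.0191). The authors' deposited table gave log2 folds of -5.69 for CXCL8, -2.32 for TNFAIP2, -2.16 for CENPE, -1.84 for CENPF, -0.98 for TTK, 1.41 for KRT8, 0.98 for LSR, 1.41 for DDIT4 and 0.79 for SLC7A5. Folds of the called genes rose with GC content, with a Spearman correlation of 0.418 across genes, which are not independent replicates, against 0.0534 in the libraries labelled ARID3A-GFP. Against random lists matched on GC content and length, the share of G2/M genes lowered lay at percentile 98.8 in the libraries labelled ARID3B+RFP and 99.99 in those labelled ARID3A-GFP. In ARID3B+RFP the share of epithelial genes raised lay at percentile 92.0 of such lists, not beyond the GC trend, and that of stress response genes at 99.2.

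The changes under ARID3A-GFP and ARID3B+RFP were then set side by side to ask whether the paralogs act on shared genes. CCND2, TIMP3, GLI2, GRB10, TNS1 and FAM155B rose in both, and HAPLN1, CXCL1, IL1A, MEIS3P1 and NREP fell in both. The overlap was 2512 genes raised and 2636 lowered in both comparisons of 5900 genes listed in both, against 1227 and 1336 expected by chance. Both comparisons used the same 3 control libraries, whose values were not used here singly, so part of the excess may come from shared controls. The covariance of the folds was 2.49, against 0.0244 calculated for unchanged groups that share a control. The 2.49 is over genes at p under 0.05 in both comparisons, and the 0.0244 does not allow for that selection, which raises a covariance by itself. Folds correlated with r 0.970 across genes, which are not independent replicates. Directions were opposite in 16 genes, among them SAMD9, a restriction factor of the interferon response, with log2 folds in the authors' deposited table of 1.02 under ARID3A-GFP and -0.42 under ARID3B+RFP. SAMD9 and the genes compared next were chosen after their values were seen. In group FPKM, which was not tested, 53 genes were at least 2-fold higher and 96 at least 2-fold lower in the libraries labelled ARID3B+RFP than in those labelled ARID3A-GFP, of 11854 genes. This ratio followed GC content, with a Spearman correlation of 0.680 across genes, so the genes compared are not separated from that trend. SAMD9 stood at 22.1 FPKM in ARID3A-GFP and 6.39 in ARID3B+RFP, VCAN at 9.41 and 2.42, the mucin MUC1 at 31.9 and 11.7, CENPF at 22.9 and 8.66, and the interferon-induced IFIT2 at 15.1 and 5.54. Higher in ARID3B+RFP were CSF1, at 0.463 and 2.70 FPKM, PDZK1IP1 at 4.11 and 14.0, the Ras effector RASSF4 at 1.37 and 4.78, and the calcium-binding S100A9 at 3.34 and 8.63.

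The population labelled high/high was compared with the control to ask what both proteins do together. TIMP3, GLI2, CCND2, GRB10, BGN, FAM155B, TNS1, MMP2 and UNC13A, a synaptic vesicle priming gene, rose most. The cell cycle inhibitor CDKN2B fell most, followed by CXCL1, IL1A, IL1B, the glycolipid enzyme UGT8, HAPLN1, the axonal gene DPYSL5 and NREP. RPL39L, whose reads overlap those of RPL39, and MEIS3P1 were also among the strongest decreases. NF-kB targets such as CXCL2 were lowered as a group, and growth factor receptors and MAPK response genes were raised, with IGFBP3, IGF1R, FGFR3 and the stress factor ATF3. The authors' deposited table gave log2 folds of 9.00 for TIMP3, 8.57 for GLI2, 8.39 for CCND2, 8.28 for GRB10, 7.96 for BGN, 7.35 for FAM155B, 7.14 for TNS1, 7.05 for MMP2, 6.86 for UNC13A, 3.24 for IGFBP3, 2.07 for IGF1R, 2.36 for FGFR3 and 2.46 for ATF3. It gave -7.81 for CDKN2B, -7.66 for CXCL1, -7.34 for MEIS3P1, -7.32 for IL1A, -7.30 for RPL39L, -7.29 for IL1B, -7.07 for UGT8, -7.03 for HAPLN1, -7.00 for DPYSL5, -6.61 for NREP and -5.09 for CXCL2 in the authors' deposited table. The authors' DESeq with Benjamini-Hochberg called 3748 genes, 2175 raised and 1573 lowered. NF-kB targets counted 0 raised and 14 lowered of 27, or 2 and 15 adjusted over the list alone (adjusted p 0.000194). Receptor and MAPK genes counted 14 raised and 5 lowered of 37, with the same counts adjusted over the list alone (adjusted p 0.0318), and no longer passed without chromosomes 4, 6 and X (adjusted p 0.0566), where 13 of the 18 members left in the comparison were raised. Against random lists matched on chromosome the raised share lay at percentile 99.965. This list was not set against lists matched on GC content, so its rise is not separated from the GC trend given below. G2/M genes counted 0 raised and 3 lowered of 34, also adjusted over the list alone, passed no test against listed genes, and were raised less often than all expressed genes (adjusted p 0.0404). Among called genes the Spearman correlation of fold with GC content was 0.466 across genes, and 9.97% of the genes in the lowest GC group were raised against 80.6% in the highest.

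The population labelled high/low held the most ARID3B of all groups, against its label, and the fewest genes called. The smallest absolute log2 fold listed for it was 0.728, so smaller changes were not called there. TIMP3, CCND2, GLI2, BGN, GRB10, MMP2 and TNS1 rose with the axon guidance ligand SLIT3. HAPLN1, IL1B and CXCL1 fell with FAM109B, the epithelial flippase subunit TMEM30B, SDR42E1, HOMER2, CYSTM1, RPL39L and MEIS3P1. Mesenchymal genes rose as a group, with the calcium-binding S100A4, the intermediate filament VIM and the matrix gene SPARC, and so did interferon response genes such as OASL and EPSTI1. The authors' deposited table gave log2 folds of 9.04 for TIMP3, 8.33 for CCND2, 8.20 for GLI2, 8.09 for BGN, 7.76 for GRB10, 6.87 for MMP2, 6.83 for TNS1, 6.40 for SLIT3, 3.55 for S100A4, 3.22 for VIM, 2.29 for SPARC, 3.58 for OASL and 1.81 for EPSTI1. It gave -7.70 for HAPLN1, -7.45 for IL1B, -7.36 for CXCL1, -7.20 for RPL39L, -6.87 for FAM109B, -6.62 for MEIS3P1, -6.38 for TMEM30B, -6.31 for SDR42E1, -6.17 for HOMER2 and -6.00 for CYSTM1 in the authors' deposited table. The authors' DESeq with Benjamini-Hochberg called 1708 genes, 891 raised and 817 lowered, all at least 2-fold. Mesenchymal genes counted 12 raised and 3 lowered of 24, or 12 and 4 adjusted over the list alone (adjusted p 0.00215). Interferon genes counted 9 raised and 1 lowered of 39, or 10 and 2 adjusted over the list alone (adjusted p 0.0195), and NF-kB targets 0 and 11 of 27, or 2 and 11 adjusted over the list alone (adjusted p 0.00237). Receptor and MAPK genes counted 9 raised and 1 lowered of 37, or 11 and 1 adjusted over the list alone (adjusted p 0.0318), and no longer passed without chromosomes 4, 6 and X (adjusted p 0.138), where 8 of the 13 members left in the comparison were raised. Against random lists matched on chromosome their raised share lay at percentile 99.97. Lists matched on GC content were not run for them. Folds of the called genes correlated with GC content here too (Spearman 0.380 across genes).

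The population labelled low/high held the most ARID3A of all groups, against its label, and the most genes called. The number of calls does not measure the size of the response: the smallest absolute log2 fold listed was 0.0841 in low/high and 0.728 in high/low. At least 8-fold changed 502 genes in low/high and 527 in high/low. CCND2, TIMP3, GLI2, GRB10, FAM155B, TNS1, MMP2, BGN and MT1E rose most. The calcium channel subunit CACNA2D1, HAPLN1, PDZK1IP1, IL1B, CDKN2B, MEIS3P1, FAM109B, the cell adhesion gene RADIL, the thyroid hormone deiodinase DIO2 and FHL1 fell most. Ribosomal protein genes rose together, RPL7, RPL7A, RPL12 and RPL11 among them, as did respiratory chain genes such as NDUFB9. Targets of p53 rose, with BAX, the cell cycle inhibitor CDKN1A, BTG2 and GADD45A, while antigen presentation genes such as HLA-B, HLA-C and CD74 fell. The authors' deposited table gave log2 folds of 8.80 for CCND2, 7.98 for TIMP3, 7.20 for GLI2, 7.14 for GRB10, 6.60 for FAM155B, 6.55 for TNS1, 6.31 for MMP2, 6.09 for BGN and 5.53 for MT1E. It gave -7.89 for CACNA2D1, -7.87 for HAPLN1, -7.01 for PDZK1IP1, -6.93 for IL1B, -6.67 for CDKN2B, -6.32 for MEIS3P1, -6.26 for FAM109B, -6.21 for RADIL, -6.06 for DIO2 and -6.04 for FHL1 in the authors' deposited table. The authors' DESeq with Benjamini-Hochberg called 9022 genes, 4607 raised and 4415 lowered, of which 2520 changed at least 2-fold, 949 raised and 1571 lowered.

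Ribosomal protein genes in the population labelled low/high counted 54 raised and 3 lowered of 64, with the same counts adjusted over the list alone (adjusted p 5.15e-12). In the other comparisons they counted 19 and 7 in ARID3A-GFP, 11 and 1 in ARID3B+RFP, 19 and 1 in high/high and 0 and 0 in high/low, or 18 and 7, 5 and 1, 25 and 1 and 0 and 0 adjusted over the list alone. By FPKM, which was not tested, 31 were higher and 33 lower in low/high than in high/low, with a median log2 ratio of -0.02. The authors' deposited table gave log2 folds of 0.92 for RPL7, 0.94 for RPL7A, 0.84 for RPL12, 0.72 for RPL11, 1.17 for NDUFB9, 1.20 for BAX, 0.86 for CDKN1A, 2.28 for BTG2, 0.49 for GADD45A, -1.37 for HLA-B, -1.39 for HLA-C and -1.52 for CD74. Respiratory chain genes counted 28 raised and 7 lowered of 45, or 31 and 8 adjusted over the list alone (adjusted p 0.0273). NF-kB targets such as CSF1, CXCL2 and TNFAIP2 counted 0 raised and 24 lowered of 27, also adjusted over the list alone (adjusted p 5.62e-07), with log2 folds of -5.26, -4.02 and -2.48 in the authors' deposited table. The p53 targets counted 17 raised and 3 lowered of 26, also adjusted over the list alone (adjusted p 0.0117). Stress response genes such as TRIB3 and SHMT2 counted 19 raised and 4 lowered of 30, or 20 and 4 adjusted over the list alone (adjusted p 0.0191). Antigen presentation genes counted 0 raised and 9 lowered of 12, also adjusted over the list alone (adjusted p 0.0106). Most of these lie on chromosome 6, where 72.6% of called genes were lowered. Without chromosomes 4, 6 and X neither their decrease nor the rise of respiratory chain genes passed (adjusted p 0.159 and 0.0859), with 4 of 4 members left in the comparison lowered and 26 of 37 raised. Against random lists matched on chromosome, the shares lay at percentile 99.7 for antigen presentation genes and 100 for respiratory chain genes. Epithelial genes, with 17 raised and 3 lowered of 31, or 17 and 4 adjusted over the list alone, and G2/M genes such as CCNA2, AURKA and TPX2, with 1 raised and 16 lowered of 34, or 1 and 15 adjusted over the list alone, passed against listed genes (adjusted p 0.0273 and 0.0103). CCNA2 lies on chromosome 4, where 93.0% of called genes were lowered. Neither list passed against all expressed genes (adjusted p 0.0563 and 0.180), and against lists matched on GC content and length they lay at percentile 96.7 and 94.0. G2/M genes were, however, raised less often than listed genes and than all expressed genes (adjusted p 0.00205 and 0.00110), with the raised share at percentile 0.02 of the lists matched on GC content and length.

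**Figure D3:**
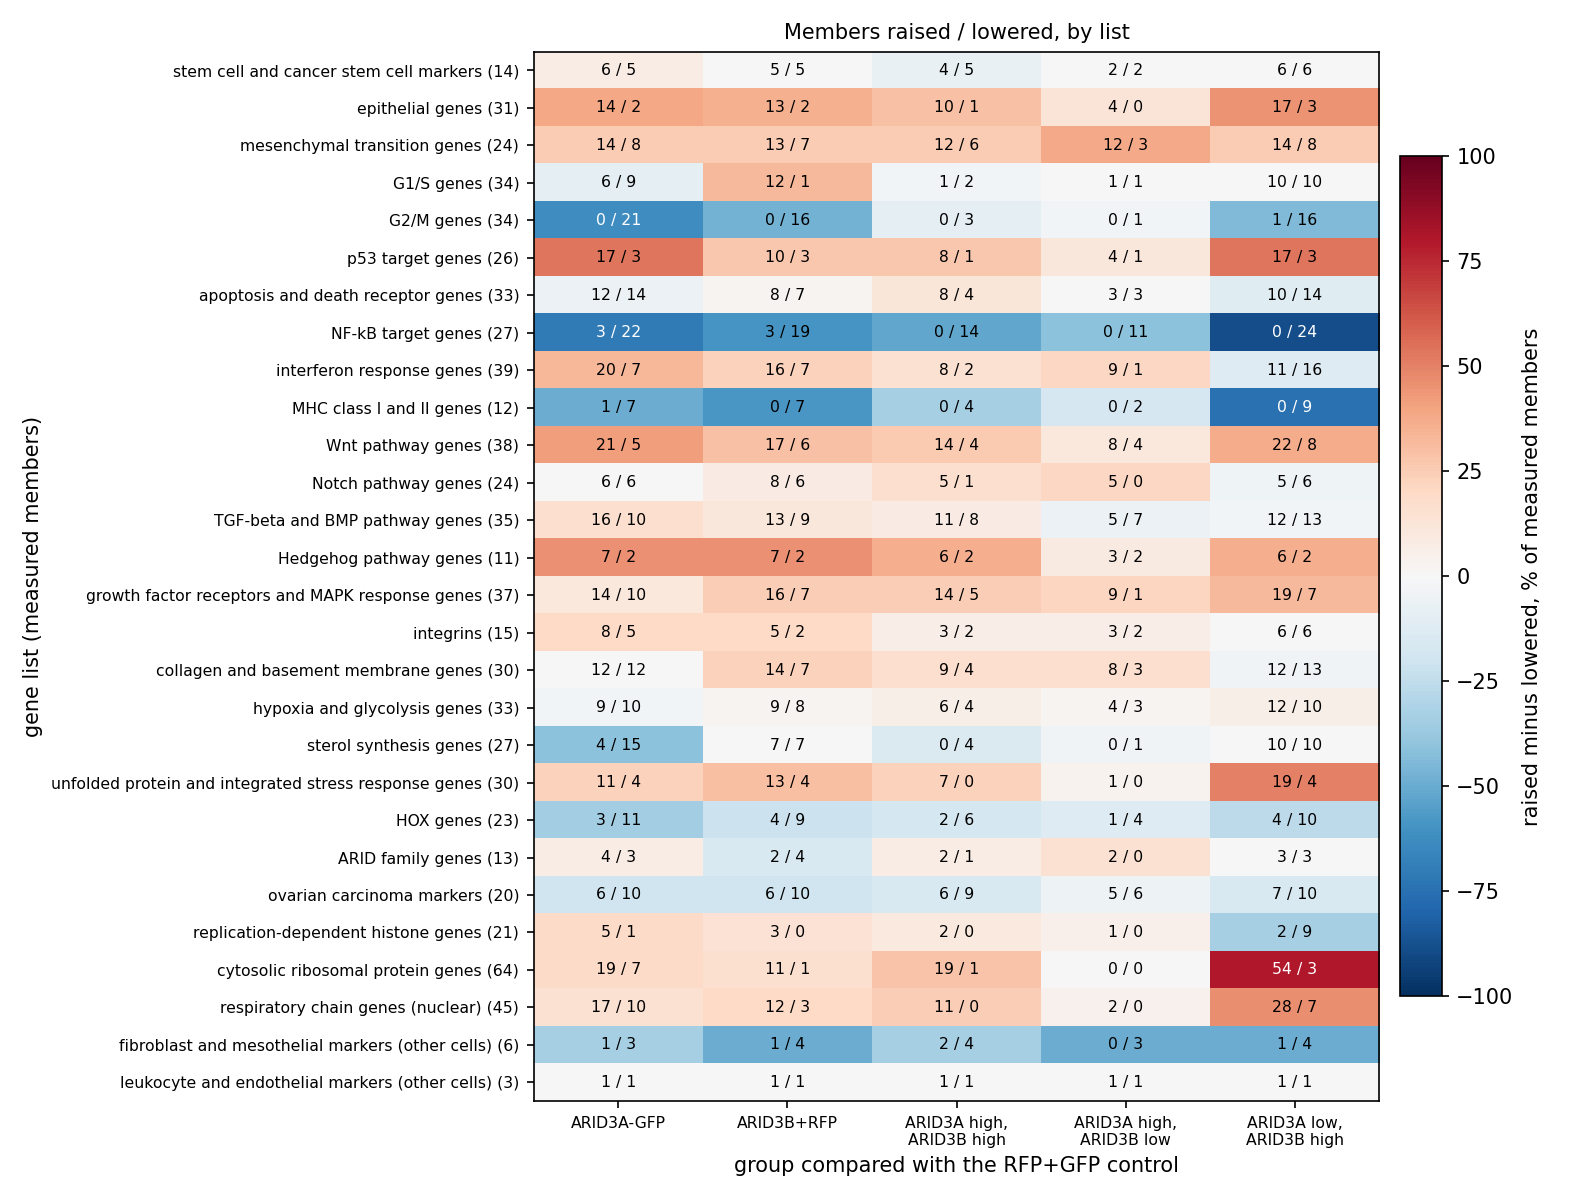
Members raised and lowered at an adjusted p under 0.05 in each of 28 gene lists and 5 comparisons with the control, printed as raised / lowered. Colour gives raised minus lowered members in percent of measured members, and NF-kB targets are lowered throughout, from 11 to 24 of 27.

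The populations carrying both proteins were set against each single transduction to ask which single changes recur. CCND2, TIMP3, GLI2, GRB10, TNS1 and MMP2 rose in all 5 comparisons, and HAPLN1, CXCL1, IL1A, IL1B and MEIS3P1 fell in all 5. The population labelled high/high shared 1888 raised and 1465 lowered genes with ARID3A-GFP, against 974 and 669 expected, and 1881 and 1414 with ARID3B+RFP, against 1011 and 602. The population labelled high/low shared 852 raised and 814 lowered genes with ARID3A-GFP, against 456 and 367 expected, and 837 and 809 with ARID3B+RFP, against 451 and 357. The population labelled low/high shared 2969 raised and 3428 lowered genes with ARID3A-GFP, against 1395 and 1821 expected, and 2967 and 2796 with ARID3B+RFP, against 1522 and 1358. The same 3 control libraries entered every comparison, so part of each excess may come from shared controls. Across genes, which are not independent replicates, the fold in a population carrying both proteins rose with the sum of the single folds with a slope of 0.594 in high/high, 0.554 in high/low and 0.510 in low/high. On the mean of the single folds the slopes were 1.19, 1.11 and 1.02. Simulated unchanged groups that share a control gave a slope on the sum of 0.333 over all genes and 0.495 over genes at p under 0.05 in all 3 comparisons, as selected here. That selection kept 45.6 simulated genes on average, against 4253, 2899 and 5653 genes in the data, so it is no close reference. ARID3A and ARID3B were both raised in each single transduction, so the slopes do not show whether the effects of the proteins add. Genes called in a population carrying both and listed in neither single comparison numbered 161, 18 and 1225 of the genes called in the populations labelled high/high, high/low and low/high, or 4.30, 1.05 and 13.6%. Passing in one comparison and not in another was not tested as a difference.

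The populations carrying both proteins were compared with each other by group FPKM, which was not tested, to ask what changes with the balance of the proteins as labelled. Sterol synthesis genes, which are induced when cell cholesterol is low, were higher in the population labelled low/high, with INSIG1, MSMO1 and IDI1. The immediate early gene EGR1 and the growth factor binding IGFBP7 were also highest there, while the stress phosphatase regulator PPP1R15A, the phosphatase DUSP5 and the placental-type alkaline phosphatases ALPP and ALPPL2 were highest in the population labelled high/low. The scaffold gene AKAP12 was lowest and the hormone subunit CGA highest in the population labelled high/high. Of 11882 genes 387 had a range of at least 2-fold, and 291 of these were lowest in the population labelled high/high. With a pseudocount of 0.1 FPKM 1048 genes had such a range. Ratios of high/high to ARID3A-GFP followed GC content, with a Spearman correlation of 0.796 across genes. In the order high/high, high/low and low/high, INSIG1 was 15.4, 20.6 and 50.6 FPKM, MSMO1 14.0, 28.1 and 43.4, IDI1 12.3, 25.1 and 38.2, EGR1 8.35, 12.8 and 30.6, and IGFBP7 0.946, 0.926 and 4.81. PPP1R15A was 26.3, 76.2 and 32.5 FPKM, DUSP5 6.65, 20.6 and 8.51, ALPP 58.9, 83.1 and 29.1, ALPPL2 16.7, 26.6 and 8.85, AKAP12 2.53, 8.34 and 9.26, and CGA 8.67, 7.26 and 1.97. In the ratio of low/high to high/low, 24 of 27 sterol genes were higher, and the list's median log2 ratio of 0.26 lay at percentile 99.89 of 10000 random lists matched on level. NF-kB targets had a median of -0.56, integrins -0.49 and interferon genes -0.28, each at percentile 0. At percentile 0 as well lay antigen presentation genes with a median of -0.38, collagen genes with -0.24 and stress response genes with -0.30, of which 24 of 30 were lower although they were raised as a group in low/high against the control. In the ratio of high/high to high/low, G2/M genes had a median of -0.33 and integrins -0.67, each at percentile 0 of lists matched on level, not on GC content.

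In all 5 comparisons 777 genes were raised and 783 lowered, and of the genes called in all 5, 0 were raised in some and lowered in others. In simulated unchanged groups that share a control, 99.9% of the genes at p under 0.05 in a pair of comparisons had the same direction. Those simulations held on average 0 genes at an adjusted p under 0.05 in both. They therefore do not tell how far the shared control libraries set the direction of called genes, and part of the agreement may come from them. Without the population labelled high/low, which had the fewest calls, 1730 genes were raised and 1358 lowered in the other 4. Among mesenchymal genes, ACTA2, LOX, MMP14, MMP2, S100A4, SNAI2, SPARC, TGFBI, TNC, TWIST1 and VIM rose in all 5, while CDH2, FN1 and ZEB1 fell in all 5. Outside the population labelled high/low, mesenchymal genes counted 14 raised and 8 lowered of 24 in ARID3A-GFP, 13 and 7 in ARID3B+RFP, 12 and 6 in high/high and 14 and 8 in low/high, or 15 and 8, 13 and 7, 13 and 6 and 14 and 9 adjusted over the list alone. Interferon genes counted 20 and 7, 16 and 7, 8 and 2, and, with more lowered than raised, 11 and 16 of 39, or 21 and 7, 16 and 7, 8 and 2 and 11 and 17 adjusted over the list alone. Neither list passed against listed genes in these 4 comparisons. Against all expressed genes the rise of mesenchymal genes passed in ARID3A-GFP, ARID3B+RFP and high/high (adjusted p 0.0139, 0.0107 and 0.00127) and that of interferon genes in ARID3A-GFP (adjusted p 0.00950). The NF-kB targets BIRC3, CSF1, CSF2, CXCL1, CXCL2, CXCL3, CXCL8, IL1A, IL1B, SAA1 and TNFAIP2 fell in all 5. A group of 32 genes was listed at 0 FPKM in all 5 groups and lowered in all 5, among them the Wnt ligand WNT5A, the sulfotransferase CHST2 and the endothelin receptor EDNRA, which were chosen after their values were seen. The shared changes were uneven over chromosomes. Genes of chromosome 4 were lowered among called genes in 91.5, 93.9, 93.4, 90.1 and 93.0% and genes of chromosome 6 in 71.1, 77.3, 80.9, 78.1 and 72.6%, in the order ARID3A-GFP, ARID3B+RFP, high/high, high/low and low/high as labelled. Genes of chromosome X were raised in 71.5, 68.3, 71.6, 63.8 and 67.5%. Other chromosomes were skewed as well: genes of chromosome 21 were lowered in 91.2, 86.6, 83.8, 82.4 and 88.7% and genes of chromosome 11 in 75.0, 69.1, 56.3, 56.1 and 71.3%. Leaving out chromosomes 4, 6 and X keeps these in. Without chromosomes 4, 6 and X the genes called in all 5 numbered 1369, with 719 raised and 650 lowered, and NF-kB targets still fell more often than other listed genes in all 5 comparisons. In the FPKM ratio of ARID3B+RFP to ARID3A-GFP with the GC trend removed, 43.4% of 378 expressed chromosome 4 genes were higher. The GC adjustment centres such a share near 49.9%, the mean of its shuffles, and it covers more than called genes. It is therefore not on the scale of the shares above. For ARID3B+RFP against the control, GC-matched shuffles gave a mean of 30.1% raised on chromosome 4.

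**Figure D4:**
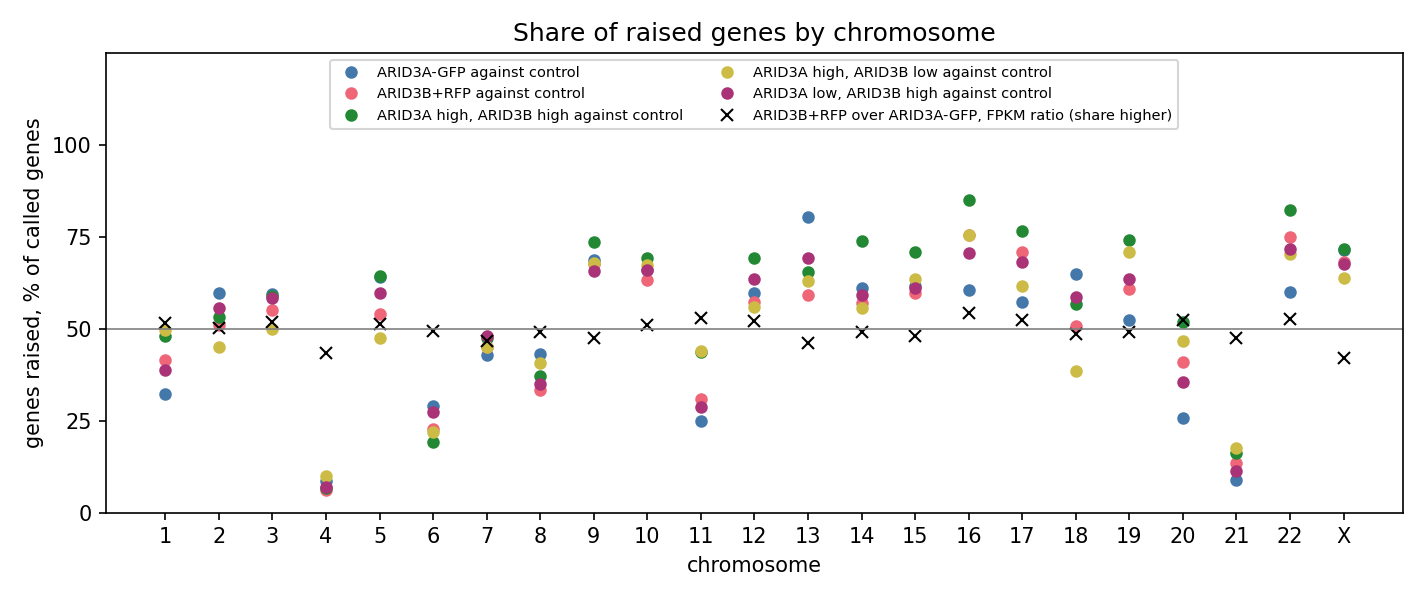
Share of called genes that were raised (percent) on each chromosome in the 5 comparisons with the control, without GC adjustment. Crosses give the share of all expressed genes higher in ARID3B+RFP than in ARID3A-GFP by FPKM with the GC trend removed, a different scale. Chromosome 4 lies between 6.14 and 9.86% raised in the comparisons with the control, and at 43.4% in the GC-adjusted ratio between the transduced groups.

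Stem cell markers moved both ways, with the neural filament NES raised and the aldehyde dehydrogenases ALDH1A1 and ALDH1A3 lowered in every comparison, and TNF and PROM1 were listed in none. In the authors' deposited table the log2 folds of NES were 4.98, 5.87, 5.40, 5.22 and 5.32 and those of ALDH1A1 -2.15, -3.29, -4.50, -3.12 and -3.93, in the order of groups used for the chromosomes, which holds for all series of values below. CD44, a hyaluronan receptor, was lowered in 3 comparisons, at -1.03 under ARID3A-GFP, -0.68 in high/high and -0.46 in low/high in the authors' deposited table. Signalling genes moved both ways as well. The Notch ligands JAG1 and DLL1 and the BMP antagonist NOG rose throughout, the activin subunit INHBB fell throughout, and in the Hedgehog pathway GLI2 rose and the receptor SMO fell in all 5 comparisons. The authors' deposited table gave log2 folds of 1.62, 1.81, 1.68, 1.37 and 1.47 for JAG1, 3.18, 4.12, 3.32, 4.16 and 3.68 for NOG, and -3.84, -2.69, -5.04, -4.53 and -4.25 for INHBB. No list test against listed genes passed for these lists. Against all expressed genes the rise of Hedgehog genes passed in ARID3B+RFP and high/high (adjusted p 0.0322 and 0.0224) and the decrease of TGF-beta and BMP genes in high/low (adjusted p 0.0239). As raised and lowered, stem cell markers counted 6 and 5, 5 and 5, 4 and 5, 2 and 2, and 6 and 6 of 14. Notch genes counted 6 and 6, 8 and 6, 5 and 1, 5 and 0, and 5 and 6 of 24. TGF-beta and BMP genes counted 16 and 10, 13 and 9, 11 and 8, 5 and 7, and 12 and 13 of 35. Hedgehog genes counted 7 and 2, 7 and 2, 6 and 2, 3 and 2, and 6 and 2 of 11. Adjusted over the list alone, the counts under ARID3A-GFP were 6 and 5 for stem cell markers, 6 and 6 for Notch, 16 and 11 for TGF-beta and BMP, and 7 and 2 for Hedgehog genes.

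Matrix and adhesion genes rose in part, with the basement membrane collagen COL4A1 and the integrin subunit ITGB5 raised throughout. Of the ovarian carcinoma markers 6 fell throughout, the secreted proteins LCN2 and SLPI among them, and 5 rose throughout, namely MUC16, KLK5, KLK6, KLK8 and CRABP2. The homeobox genes HOXB2 and HOXB6 fell throughout. The hormone-like peptide ADM of the hypoxia list rose and the kinase PDK3 fell, the death receptor TNFRSF21 rose, and the chromatin gene JARID2 of the ARID family fell in 4 comparisons. The authors' deposited table gave log2 folds of 1.83, 2.23, 2.40, 1.98 and 1.76 for COL4A1, -4.46, -4.33, -4.93, -4.48 and -4.43 for LCN2, -4.66, -4.86, -5.05, -4.23 and -5.07 for SLPI, and -2.74, -2.37, -2.34, -2.03 and -2.43 for HOXB2. No list test against listed genes passed for the lists of this group. Against all expressed genes the decrease of ovarian markers passed in high/high and high/low (adjusted p 0.00218 and 0.00758), their rise in high/low (adjusted p 0.0404), and the rise of collagen genes in ARID3B+RFP and high/low (adjusted p 0.0434 and 0.00527). Collagen genes counted 12 and 12, 14 and 7, 9 and 4, 8 and 3, and 12 and 13 of 30 as raised and lowered. Integrins counted 8 and 5, 5 and 2, 3 and 2, 3 and 2, and 6 and 6 of 15. Ovarian markers counted 6 and 10, 6 and 10, 6 and 9, 5 and 6, and 7 and 10 of 20. HOX genes counted 3 and 11, 4 and 9, 2 and 6, 1 and 4, and 4 and 10 of 23. Hypoxia and glycolysis genes counted 9 and 10, 9 and 8, 6 and 4, 4 and 3, and 12 and 10 of 33. Apoptosis genes counted 12 and 14, 8 and 7, 8 and 4, 3 and 3, and 10 and 14 of 33. ARID family genes counted 4 and 3, 2 and 4, 2 and 1, 2 and 0, and 3 and 3 of 13, ARID3A and ARID3B included. Adjusted over the list alone, the counts under ARID3A-GFP were 12 and 12 for collagen, 8 and 5 for integrin, 6 and 10 for ovarian, 3 and 11 for HOX, 9 and 10 for hypoxia, 12 and 14 for apoptosis and 4 and 3 for ARID family genes.

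Sterol synthesis genes fell under ARID3A-GFP in part, with MSMO1, SC5D and FDFT1, whereas the desaturase SCD rose there, in ARID3B+RFP and in low/high. Histone genes, markers of fibroblast and mesothelial cells and markers of leukocytes and endothelium also moved both ways, with the matrix gene FBLN1 and the mesothelial LRRN4 lowered, COL1A1 raised in 4 comparisons, the macrophage receptor CSF1R raised and the macrophage glycoprotein CD68 lowered. In the authors' deposited table the log2 folds were -1.07 for MSMO1, -0.81 for SC5D and -0.91 for FDFT1 under ARID3A-GFP, and those of FBLN1 were -3.09, -2.03, -3.26, -2.75 and -3.36. CSF1R had 2.99, 3.76, 3.69, 3.79 and 3.37 and CD68 -2.20, -2.02, -1.75, -1.45 and -2.27 in the authors' deposited table. No list test against listed genes passed. Sterol genes counted 4 raised and 15 lowered of 27 under ARID3A-GFP, also adjusted over the list alone, which passed only against all expressed genes (adjusted p 0.0275). They counted 7 and 7 under ARID3B+RFP and 10 and 10 in low/high. Against all expressed genes the decrease of fibroblast and mesothelial markers passed in high/high and high/low (adjusted p 0.0159 and 0.0239), and histone genes were lowered less often in ARID3B+RFP (adjusted p 0.0423). Histone genes counted 5 and 1, 3 and 0, 2 and 0, 1 and 0, and 2 and 9 of 21. Fibroblast and mesothelial markers counted 1 and 3, 1 and 4, 2 and 4, 0 and 3, and 1 and 4 of the 6 measured. Leukocyte and endothelial markers counted 1 and 1 of the 3 measured in every comparison. Adjusted over the list alone, the counts under ARID3A-GFP were 4 and 1 for histone genes, 1 and 3 for fibroblast and mesothelial markers, and 1 and 1 for leukocyte and endothelial markers.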

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

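The tests of how comparisons and FPKM columns pair, of the covariance that shared controls give and of whole chromosomes were chosen only after the results were seen, as was the removal of the GC trend from the test of exchanged labels and from the neighbour correlations. Directions below rest on labels that the transgenes' levels go against.

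Some genes were called in opposite directions in a pair of comparisons with the same control, and the difference was not tested. There were 29 such genes between ARID3A-GFP and the population labelled low/high, 17 between ARID3B+RFP and low/high, 16 between ARID3A-GFP and ARID3B+RFP, 2 between high/high and low/high (ADAMTSL4 and AFAP1-AS1) and 1 between ARID3B+RFP and high/high (DNAJB6). The genes named here were chosen after their values were seen. In the authors' deposited table the immediate early gene EGR1 had log2 folds of -1.65 in ARID3B+RFP and 1.18 in low/high, and FOS -0.87 and 0.91. The interferon-induced MX2 had 0.70 in ARID3A-GFP and -2.21 in low/high, and THBS1, an inhibitor of blood vessel growth, 0.25 and -0.90, in the authors' deposited table. TRAF1, an adaptor of TNF receptors, had 0.92 in ARID3A-GFP and 1.85 in ARID3B+RFP against -0.90 in low/high in the authors' deposited table.

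ARID3A and ARID3B levels went against the labels: ARID3B was highest in the population labelled high/low, and ARID3A was raised in ARID3B+RFP. In all 10 pairs of comparisons the difference of deposited folds correlated best with the FPKM ratio of the columns of the same names, which argues against columns and comparisons naming the populations differently. For an exchange of the labels high/low and low/high, genes differing between ARID3B+RFP and ARID3A-GFP had a median log2 ratio of -0.236 signed towards ARID3B+RFP, away from an exchange, but with the GC trend removed it was 0.0347 over 77 genes, within their random range of -0.0593 to 0.0587, so an exchange stays open. ARID3A-GFP cells or RNA mixed into ARID3B+RFP would need a share of 54.3%. Below the level this share needs, divided by 2, lay 14 genes in ARID3B+RFP, where more than 20 were needed to exclude mixing, so mixing may explain the ARID3A level and stays open, as does a real rise of ARID3A under ARID3B.

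A single response was shared by all 5 comparisons, with CCND2, TIMP3 and GLI2 raised and HAPLN1, CXCL1 and IL1A lowered. The covariance of the folds was at least 55.2 times that calculated for unchanged groups that share a control. That reference does not allow for the selection of genes at p under 0.05, which raises the ratio by itself, so the ratio does not decide. In simulated unchanged groups on average 0 genes passed an adjusted p under 0.05 in both of a pair. In ARID3A-GFP and ARID3B+RFP 2512 were raised and 2636 lowered in both. The simulated folds had the spread that the p-values assume, so the 0 follows from the adjustment. It cannot decide on control libraries that deviate by more than that spread, which stays open. A candidate explanation is that the control cells differed from the transduced cells in chromosome copy number: folds of genes 10 to 20 places apart correlated at 0.114 or more, above all 1000 shuffles, but the margin of 0.05 set in advance over the ratio of ARID3B+RFP to ARID3A-GFP (0.201) was not met, and with the GC trend removed from both (ratio 0.0106, folds from 0.0275 in high/low and 0.0493 in high/high to 0.176) it was missed in these 2 populations, so this test leaves it open. For the number of whole chromosomes, 3 of 23 (4 and 6 lowered, X raised) lay outside 1000 GC-matched shuffles on the same side in all 5 comparisons. In FPKM ratios of all expressed genes with the GC trend removed, 0 lay outside for ARID3B+RFP over ARID3A-GFP. For low/high over high/low 2 others did (7 higher, 19 lower). The count of 3 is bounded by high/low, which had the fewest calls. Outside the shuffles lay 17, 14, 9, 3 and 19 of 23 chromosomes in ARID3A-GFP, ARID3B+RFP, high/high, high/low and low/high. Of the 1560 genes called in all 5, 1369 remained without chromosomes 4, 6 and X. This argues against copy number of these 3 acting on their own genes alone as the whole cause. ARID3A and ARID3B, both raised in all 5 groups though the labels give neither to all, are the biological explanations: genes called in all 5 had a median ratio of absolute folds of 0.966 between the groups with the most and the least ARID3A, which leaves ARID3A open, and ARID3B was not tested. NF-kB targets fell off chromosomes 4 and 21 too, which does not tell the transgenes from other differences of the control cells.

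Genes of mitosis and many others were lower in some groups. Between the population labelled high/high and ARID3A-GFP, removing the trend with GC content and length left 4.01% of the genes at least 2-fold lower (59 of 1472), so a GC trend between libraries is a candidate explanation for most of them. Beyond that trend, G2/M genes in high/high lay at percentile 0.24 of matched random lists, with a median log2 ratio of -0.81 against -0.50, so lower expression of cell division genes there is a hypothesis. Against the control, the share of G2/M genes lowered lay at percentile 98.8 or above of GC-matched lists in ARID3A-GFP and ARID3B+RFP, which argues against the GC trend as the whole cause in these groups. Against random lists matched on chromosome, the share of G2/M genes lowered lay at percentile 100 in ARID3A-GFP, with 61.8% against a random median of 29.4%. In ARID3B+RFP it lay at percentile 99.9, with 47.1% against 23.5%. These values argue against copy number of whole chromosomes as the whole cause of the G2/M decrease in these 2 groups. Lists were matched on chromosome or on GC content and length, not on both, so the GC trend and whole chromosomes acting together were not tested. That combination, copy number of parts of chromosomes and the transgenes stay open for them.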

How the results depend on the processing

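The settings of at least 1 FPKM, of leaving out a population or chromosomes 4, 6 and X, of recentred folds and of the expressed background were chosen only after the results were seen. Recentring shifts all genes of a comparison alike, by 0.12 in ARID3A-GFP and -0.15 in high/low, too little against the listed folds to test their directions. At an absolute log2 fold of at least 1, the called genes numbered 2093 in ARID3A-GFP, 2722 in ARID3B+RFP and 2520 in the population labelled low/high, and the shared genes 1701 for ARID3A-GFP with ARID3B+RFP, 1527 and 1812 for high/high and 1762 and 2066 for low/high with ARID3A-GFP and ARID3B+RFP. The balance of raised and lowered genes turned at that fold to 1061 and 1661 in ARID3B+RFP and 949 and 1571 in low/high, in the overlaps to 660 and 867 for high/high and 629 and 763 for high/low with ARID3A-GFP and to 845 and 967 for high/high, 728 and 769 for high/low and 795 and 1271 for low/high with ARID3B+RFP, and at an adjusted p under 0.01 to 2510 and 2519 in ARID3B+RFP, 577 and 642 in high/low, and 554 and 639 and 542 and 635 for high/low with ARID3A-GFP and ARID3B+RFP. The genes called in all 5 turned to 719 and 650 without chromosomes 4, 6 and X. With at least 1 FPKM in the higher group, 1123 genes were called in high/low. Without high/low, 3088 genes were called in all the other comparisons, 1730 raised and 1358 lowered. Over genes of at least 10 FPKM, the slopes on the sum of single folds were 0.605, 0.589 and 0.492 in high/high, high/low and low/high. With a pseudocount of 0.1, 1048 genes had a 2-fold range between the populations carrying both proteins. The minimum fold and FPKM keep fewer genes and the omission of a comparison more by construction, and for the balance, the slopes and the pseudocount the cause was not tested. At an adjusted p under 0.01 the counts were 6410, 5029, 2506, 1219 and 7646. List tests that passed numbered 46 of 280, and 37 when genes were called at an adjusted p under 0.01 and lists still tested at 0.05, 52 against expressed genes and 36 without chromosomes 4, 6 and X. No paired analysis was possible because the replicate numbers are shared between groups but values per library were not used here. For this reason leaving out replicates, blocks and other normalizations were not run. The threshold of 0.1 was not run for ARID3A-GFP and low/high, whose lists end below it, and folds from FPKM were not run for want of a control level. Depth, which is unknown, limits all values.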

Other observations

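Among genes named for their large folds, CCND2 rose from implied control levels of 0.0226 to 0.0353 FPKM and TIMP3 from 0.0128 to 0.0326 FPKM, while HAPLN1 fell from implied levels between 6.35 and 12.9 FPKM. CXCL1 fell from implied levels of 207 to 428 FPKM to between 1.71 and 3.49 FPKM. Below 0.05 FPKM in all 5 groups lay 194 genes lowered in all 5. Genes lowered at least 8-fold outnumbered those raised at least 8-fold in each comparison, with 280 against 128 in ARID3A-GFP, 336 against 154 in ARID3B+RFP, 382 against 171 in the population labelled high/high, 350 against 177 in high/low and 369 against 133 in low/high.

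Sterol synthesis genes were higher and interferon genes lower in the population labelled low/high than in ARID3A-GFP by group FPKM, which was not tested, though ARID3A was high in both. In that ratio 25 of 27 sterol genes were higher, 36 of 36 interferon genes were lower and 64 of 64 ribosomal protein genes were higher, with median log2 ratios of 0.40, -0.48 and 0.26, against 0.08, -0.01 and 0.17 in random lists matched on level. The ratio followed GC content, with a Spearman correlation of 0.555 across genes, which are not independent replicates, and the random lists were not matched on GC content. No explanation was tested.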
